A study of Mus musculus with 18 samples.

How the data were processed

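The study measured messenger RNA by sequencing in primary mouse microglia, the resident macrophages of the brain. Per the labels, cells came from the forebrains of C57BL/6 pups of postnatal day 2 and were cultured for 7 days and, after a change of medium, for 7 more. There were 18 libraries of 6 genotypes, with 3 libraries for each genotype. It is not stated whether the 3 libraries of a genotype came from separate animals or cultures, so every p-value measures the spread between libraries. Libraries were made with oligo(dT) priming by the Smart-seq2 method from 1 ng of RNA, with 12 cycles of amplification and 0.3 ng of cDNA in the tagmentation. Paired reads of 50 bases were sequenced. This chemistry does not mark the strand, so reads of overlapping genes on opposite strands could not be told apart.

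The deposited file holds raw counts of reads per gene, made by the authors by alignment with STAR to mm10 and counting with featureCounts. Their protocol text names RSEM instead of featureCounts. The values were whole numbers and the columns carried the names of STAR alignments, so they were treated as counts. The versions, the gene annotation and the strand setting of the authors' steps were not stated. No value was normalized by the authors. The file listed 50686 gene identifiers, of which 50376 matched a symbol in GENCODE M21 (GRCm38). The 310 identifiers without a symbol held at most 0.00437% of the counts of any library.

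Total counts ranged from 8016559 to 22989116 per library. Counts came from amplified cDNA without molecular identifiers, so intervals and floors cover counting error only. A gene with no reads in a library was taken as below a floor of 3 counts there. Confidence intervals of shares were 95% Wilson intervals.

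Genes were kept by filterByExpr over the 6 genotypes, which left 13447 for testing. Libraries were scaled by the trimmed mean of M values (TMM), and expression is given as CPM, counts divided by the TMM-scaled total and multiplied by 1e6. Each value is a mean ± SD over 3 libraries. The quasi-likelihood test of edgeR 4.0.16 was applied to all 18 libraries in 1 fit with a term for each genotype, in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over the tested genes of a comparison, and an adjusted p under 0.05 was a call. All adjusted p-values of genes are from this test. The words rose and fell are used of called genes only. The comparisons were an overall test of the 6 genotypes, 9 comparisons between genotypes and the interaction of Tbk1 and Tak1 heterozygosity. With 3 libraries against 3, 10% of unchanged genes would have groups without overlap.

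The named genes were set by a rule. They are Tbk1, Map3k7 (which encodes TAK1) and Ripk1 throughout. For 5 main comparisons the rule added the 10 genes called higher and the 10 called lower with the largest fold changes, among genes with a mean of at least 5 CPM and no overlap between the libraries of both groups. For the other comparisons it took 5 in each direction, and where none passed, the 4 genes with the smallest unadjusted p. Up to 4 members were named from each gene list. Predicted genes with clone names were counted and left unnamed. Genes named outside this rule are marked as chosen after their values were seen.

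The 26 gene lists were type I interferon response, inflammatory cytokines and chemokines, NF-kB target and feedback genes, TNF-RIPK1-TBK1-TAK1 pathway components, intrinsic apoptosis, homeostatic microglia, disease-associated microglia, antigen presentation, complement and phagocytic receptors, alternative activation, cell cycle, autophagy and lysosome, cholesterol biosynthesis, glycolysis and hypoxia response, integrated and ER stress response, heat shock and immediate early genes, antioxidant response, mitochondrially encoded oxidative phosphorylation, cytosolic ribosomal proteins, sex-linked genes, and markers of astrocytes, of the oligodendrocyte lineage, of neurons, of fibroblast, mural and endothelial cells, of border macrophages and monocytes, and of other blood cells. Each was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted by the Benjamini-Hochberg method over the 26 lists of a comparison. An estimated correlation and fry were alternatives. Members were counted by the gene test over all genes tested, and also with p-values adjusted over the list alone. The genotype comparisons, tests, lists and naming rule were fixed before the data were examined.

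The alternatives fixed at that stage were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, no low-count filter, a stricter filter at a mean of 5 CPM, the replicate number as a block, a fit on only the libraries compared, a log2 fold change of at least 1, and leaving out each library in turn. After the data were seen, covariates for the mitochondrial share of counts and for 4 Y-linked genes, a correction on GC content and transcript length (available for 13431 genes), a fit on the 8 libraries with a low mitochondrial share, and fits without libraries with doubted labels were added. Agreement of fold changes between comparisons was set against 20 simulated data sets with no effect.

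The procedure was tested on simulated data with 200 changed genes. For Tbk1 heterozygous against wild type, 6.06% of the tested changed genes were called at a fold of 1.5, 39.7% at 2 and 69.4% at 4. For both alleles against wild type the shares were 9.38%, 47.8% and 76.9%. For the interaction they were 1.56%, 20.9% and 55.4%. The unchanged genes called numbered 5, 5 and 2. Each gene was drawn independently of the others, so the simulated libraries held no differences shared across genes, as of mitochondrial share or sex. These numbers therefore do not give the rate of false calls in the real libraries. No library was left out of the main results.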

Results

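Messenger RNA was counted in cultured primary microglia from mice of 6 genotypes. The labels give wild type (WT), Tbk1+/- (here Tbk1het), Tak1ΔM/+ (Tak1het), Tbk1+/- with Tak1ΔM/+ (Tbk1het Tak1het), Tbk1+/- with Ripk1 D138N on both alleles (Tbk1het Ripk1hom), and Tbk1+/- with Tak1ΔM/+ and 1 allele of Ripk1 D138N (Tbk1het Tak1het Ripk1het). TBK1 and TAK1 are kinases that restrain RIPK1 in the response to tumor necrosis factor, and the D138N change removes the kinase activity of RIPK1. The series title asks how TBK1 limits apoptosis and inflammation driven by RIPK1. Each genotype had 3 libraries, with total counts from 8016559 in Tbk1het Tak1het replicate 2 to 22989116 in Tbk1het Tak1het Ripk1het replicate 3. Between 15548 and 17433 genes had counts in a library. The most abundant gene, an rRNA gene on chromosome 17 (39846353 to 39848827), took from 10.9% of the counts (95% Wilson interval 10.92% to 10.95%) to 15.6% (15.56% to 15.6%). Mitochondrially encoded protein-coding genes took 1.24% ± 0.499 (SD, n = 3) of counts in WT, 2.01% ± 0.191 in Tbk1het, 1.12% ± 0.583 in Tak1het, 0.463% ± 0.0824 in Tbk1het Tak1het, 0.822% ± 0.644 in Tbk1het Ripk1hom and 0.839% ± 0.406 in Tbk1het Tak1het Ripk1het.

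Tbk1 RNA was at about the level of a lost allele in Tbk1het and in Tbk1het Tak1het, and near the WT level in most other libraries labelled Tbk1+/-. Tbk1 (ENSMUSG00000020115, chromosome 10, 121546455 to 121586787) had 119 ± 25.6 CPM (SD, n = 3) in WT, 57.7 ± 7.55 in Tbk1het and 59.2 ± 5.97 in Tbk1het Tak1het. Against WT the log2 fold change was -1.05 (SE 0.25) in Tbk1het, which did not pass the test (adjusted p = 0.15), and -1.01 in Tbk1het Tak1het (adjusted p = 0.0232). That call ended without WT replicate 3 (adjusted p = 0.0815) and without Tbk1het Tak1het replicate 1, 2 or 3 (0.0834, 0.0719 and 0.0587). The 3 libraries labelled Tbk1het Tak1het Ripk1het had 123, 107 and 115 CPM of Tbk1. Of the Tbk1het Ripk1hom libraries, replicates 1 and 3 had 130 and 131 CPM, and replicate 2 had 54.9. Their labels and their Tbk1 level therefore differ, and directions drawn from these 5 libraries carry that limit. Map3k7 (ENSMUSG00000028284, chromosome 4, 31964097 to 32023467), which encodes TAK1, had 13.5 ± 4.94 CPM in WT and 8.76 ± 1.33 in Tak1het, with a log2 fold change of -0.62 (adjusted p = 0.561), and passed the test in none of the comparisons between genotypes with edgeR. In Tbk1het Tak1het Map3k7 had 11.3 ± 4.62 CPM, with a log2 fold change of -0.265 against WT (adjusted p = 0.714). An allele that lacks an exon need not lower the count of a gene. Ripk1 (ENSMUSG00000021408, chromosome 13, 34002363 to 34037147) rose from 19.96 ± 3.52 CPM in WT to 58.6 ± 11.3 in Tbk1het Tak1het, a log2 fold change of 1.55 (adjusted p = 0.0433). That call ended without WT replicate 1, 2 or 3 (adjusted p = 0.133, 0.155 and 0.072) and without Tbk1het Tak1het replicate 1, 2 or 3 (0.0782, 0.0917 and 0.158). Ripk1 had 18.03 ± 4.03 CPM in Tbk1het, 32.7 ± 16.6 in Tak1het, 29.8 ± 17.5 in Tbk1het Ripk1hom and 37.1 ± 21.6 in Tbk1het Tak1het Ripk1het. Tbk1het Tak1het against Tak1het did not pass the test (log2 fold change 0.84, adjusted p = 0.355). Tbk1het Tak1het Ripk1het against Tbk1het Tak1het did not either (-0.66, adjusted p = 0.503). A rise particular to Tbk1het Tak1het is therefore not shown.

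Lyz2, which encodes a lysozyme of myeloid cells and was singled out after its values were seen, was lower in both genotypes with the Tak1 allele and WT Ripk1. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321) had 37149 ± 2162 CPM (SD, n = 3) in WT and 18291 ± 4082 in Tak1het, 49.2% of the WT mean, with a log2 fold change of -1.02 that did not pass the test (adjusted p = 0.173). In Tbk1het Tak1het it fell to 8346 ± 503 CPM, with a log2 fold change of -2.15 against WT (adjusted p = 3.02e-05) and -1.13 against Tak1het (adjusted p = 0.00515). In Tbk1het Tak1het Ripk1het it was at 40526 ± 2158 CPM, and in Tbk1het Ripk1hom at 36898 ± 7350. Without the Tak1 allele, Tbk1het had 29309 ± 9106 CPM (log2 fold change -0.34 against WT, adjusted p = 0.58). Its replicates 1, 2 and 3 were at 71.4%, 106% and 59.0% of the WT mean.

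**Figure D1:**
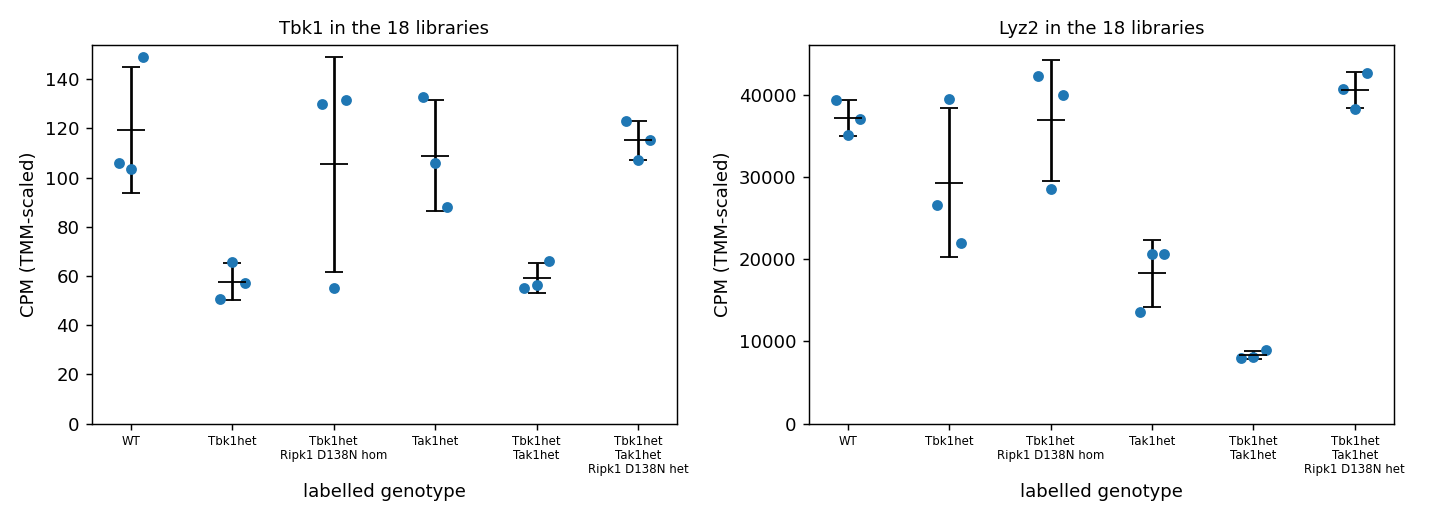
Tbk1 and Lyz2 in CPM, on totals scaled by TMM, for the 18 libraries by genotype. Points are libraries, dashes are means and bars are the SD of 3 libraries. Tbk1 has means of 57.7 in Tbk1het and 59.2 in Tbk1het Tak1het against 119 in WT, and Lyz2 has its lowest mean, 8346, in Tbk1het Tak1het.

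Among the 6 genotypes 966 of 13447 genes differed in the overall test. The interferon-induced gene Isg15 had 5.20 ± 0.971 CPM (SD, n = 3) in WT, 2.54 ± 0.623 in Tbk1het, 6.03 ± 0.360 in Tak1het and 25.8 ± 0.369 in Tbk1het Tak1het. It was at 5.36 ± 0.430 CPM in Tbk1het Tak1het Ripk1het. The proliferation marker Mki67 had 16.8 ± 7.80 CPM in WT, 49.1 ± 29.7 in Tbk1het and 1.54 ± 0.526 in Tbk1het Tak1het. The count was 639 without WT replicate 2, 482 and 604 without Tbk1het replicates 1 and 3, and 339, 376 and 320 without Tbk1het Tak1het replicates 1, 2 and 3. It was 207 with the mitochondrial share as a covariate. Leaving out the 5 libraries labelled Tbk1+/- with Tbk1 near the WT level removes 1 genotype and leaves 1 Tbk1het Ripk1hom library. A count from that fit is therefore not comparable with the 966.

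The comparison of Tbk1het with WT asks what the loss of 1 Tbk1 allele changes, and few genes passed the test. The linker histone gene Hist1h1c rose from 171 ± 12.7 CPM (SD, n = 3) in WT to 381 ± 35.8 in Tbk1het, a log2 fold change of 1.16 (adjusted p = 0.0022). Myom1, a structural protein of muscle, rose by a log2 fold change of 1.57 (adjusted p = 0.0229), and the chemokine gene Cxcl14 rose by 1.15 (adjusted p = 0.0465). Il7r, a cytokine receptor chain, fell from 101 ± 23.2 to 47.4 ± 8.66 CPM (adjusted p = 0.0441). The calcium-dependent kinase gene Camk1 (log2 fold change -0.78), the iron reductase gene Steap3 (-0.95) and Esyt1 (-0.97), a tether between the endoplasmic reticulum and the plasma membrane, also fell. These 7 genes, 3 higher and 4 lower, were those called, with 1373 at an unadjusted p under 0.05.

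None of the 26 lists had a called member in Tbk1het. Of 45 measured genes of the type I interferon response, 35 had a fold change below 0, with a median log2 fold change of -0.23 (camera adjusted p = 0.000775, and adjusted p = 0.529 with an estimated correlation). For 35 cell cycle genes the median was 0.72 (camera adjusted p = 0.00032, and adjusted p = 0.529 with an estimated correlation). The 3 libraries did not go 1 way: the mean log2 difference from WT in replicates 1, 2 and 3 was -0.63, 0.21 and -0.69 for the interferon list and 0.80, -0.34 and 0.98 for the cell cycle list. Adjusted over the list alone, 1 interferon gene and 0 cell cycle genes passed in edgeR. The interferon call ended without Tbk1het replicate 1 (adjusted p = 0.16), and both ended without Tbk1het replicate 3 (adjusted p = 0.081). In all 11 lists passed with the preset correlation and 0 with an estimated one.

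The 7 gene calls rest on few libraries. Without Tbk1het replicate 3, or without WT replicate 1 or 2, the count was 1, and Myom1, Cxcl14, Il7r, Esyt1, Steap3 and Camk1 each lost the call. The adjusted p was 0.204 for Myom1 and 0.248 for Esyt1 without WT replicate 1, and 0.269 for Il7r and 0.114 for Camk1 without Tbk1het replicate 3. Without Tbk1het replicate 1 the count was 3, and without Tbk1het replicate 2 it was 334. DESeq2 called 98 genes, limma-voom 3, and a fit on these 6 libraries alone called 0. Hist1h1c passed with each library left out in turn.

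The comparison of Tak1het with WT asks the same of the Tak1 allele, and 2 genes passed. Sgce, which encodes a sarcoglycan, rose from 8.40 ± 3.92 CPM (SD, n = 3) to 34.2 ± 1.46, a log2 fold change of 2.02 (adjusted p = 0.0247). Lox, which encodes an enzyme that crosslinks collagen and was named outside the rule after its values were seen, fell by 4.17 on the log2 scale (adjusted p = 0.00951). It did not meet the rule's conditions on mean CPM and overlap. Lox was not called under the stricter filter or in limma-voom, and it lost the call without Tak1het replicate 1 or 2. At an unadjusted p under 0.05 there were 1273 genes. Genes of cytosolic ribosomal proteins were higher as a group, with a positive fold change for 30 of 30 and a median log2 fold change of 0.29 (camera adjusted p = 6.54e-18, and adjusted p = 0.114 with an estimated correlation). No single one was called over all genes tested and 20 passed adjusted over the list alone. In all 6 lists passed at the preset correlation, and astrocyte markers and sex-linked genes, both in the lower direction, were among them. With totals not scaled by TMM, Y-linked genes had 3.02, 0 and 0 CPM in Tak1het replicates 1, 2 and 3. They had 107, 50.2 and 0 in WT, 59.8, 187 and 123 in Tbk1het, and 93.8, 99.5 and 75.9 in Tbk1het Tak1het. Sex is therefore partly mixed with genotype in Tak1het against WT. Between Tak1het and Tbk1het Tak1het sex and genotype cannot be told apart. DESeq2 called 82 genes, limma-voom 1, the fit on the 6 libraries alone 0, and the Y-linked covariate gave 63. The count was 0 without Tak1het replicate 1 or 2, 7 without Tak1het replicate 3, and 1 without WT replicate 1 or 3, and Sgce lost the call without WT replicate 1 or 3 (adjusted p = 0.0973 and 0.162) and without Tak1het replicate 1 or 2 (0.0772 and 0.105).

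The comparison of Tbk1het Tak1het with WT asks what both lost alleles change together. Genes of the type I interferon response were higher, and genes of the cell cycle lower at the preset correlation (adjusted p = 0.137 with an estimated correlation). The antiviral GTPase gene Mx1 (chromosome 16, 97447035 to 97462907) rose from 1.37 ± 0.935 CPM (SD, n = 3) in WT to 16.97 ± 3.54, a log2 fold change of 3.62 (adjusted p = 0.00647). Ifit3, whose family binds viral RNA, rose from 10.0 ± 1.48 to 79.6 ± 2.74 CPM (log2 fold change 2.99), and Rsad2, the antiviral enzyme viperin, rose from 14.4 ± 2.08 to 82.5 ± 3.98 CPM (2.52). Mki67 (chromosome 7, 135689784 to 135716361) fell from 16.8 ± 7.80 to 1.54 ± 0.526 CPM (log2 fold change -3.51, adjusted p = 0.00502). Arg1, the arginase of alternatively activated macrophages, fell from 65.7 ± 13.8 to 5.45 ± 0.887 CPM (log2 fold change -3.57, adjusted p = 0.00273).

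Other interferon-induced genes among the largest increases were Ifit3b (log2 fold change 3.09), Usp18 (2.74), which removes ISG15 from proteins, and Oas3 (2.57), a sensor of viral RNA. Increases also included Dusp5 (2.77), a phosphatase of ERK kinases, the stress-induced cytokine gene Gdf15 (2.67), Trir (2.48) and Gadd45a (2.46), which is induced by DNA damage. Genes of mitosis among the largest decreases were Shcbp1 (-3.71), the cyclins Ccnb2 (-3.54) and Ccnb1 (-3.44), the spindle genes Kif11 (-3.21) and Nusap1 (-3.20), and Ube2c (-3.19), a ubiquitin-conjugating enzyme of mitotic exit. S100a4, a calcium-binding protein, fell from 38.8 ± 12.9 to 3.46 ± 0.850 CPM (-3.46). In all 816 genes were called, 291 higher and 525 lower. The count was 426 and 325 without WT replicates 1 and 2, and 391, 411 and 288 without Tbk1het Tak1het replicates 1, 2 and 3. With the mitochondrial share as a covariate it was 211, of which 182 were among the 816, and Dusp5, Gdf15, Trir, Gadd45a, Ccnb2 and Nusap1 were not called there. Gdf15 and Gadd45a lost the call with any of the 6 libraries left out, with an adjusted p of up to 0.115 for Gdf15 (without WT replicate 1) and 0.124 for Gadd45a (without WT replicate 2).

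Of 45 interferon response genes 29 rose and 0 fell in Tbk1het Tak1het against WT by edgeR (38 and 0 adjusted over the list alone), with a median log2 fold change of 1.48 (camera adjusted p = 6.07e-42, and 0.0128 with an estimated correlation). Of 35 cell cycle genes 19 fell (27 adjusted over the list alone), with a median of -2.05 (camera adjusted p = 3.58e-24, and adjusted p = 0.137 with an estimated correlation). The mitochondrial share was 0.463% ± 0.0824 (SD, n = 3) in these libraries against 1.24% ± 0.499 in WT, and 1 of 13 mitochondrially encoded genes of oxidative phosphorylation fell (8 adjusted over the list alone; median -1.42, camera adjusted p = 2.95e-06, and adjusted p = 0.344 with an estimated correlation). Of 30 ribosomal protein genes 5 fell, among them Rpl13a (-0.73) and Rpl32 (-0.53), and 12 did adjusted over the list alone (median -0.24, camera adjusted p = 3.92e-06, and adjusted p = 0.344 with an estimated correlation). Of 26 homeostatic microglia genes 4 fell and 2 rose (7 and 3 adjusted over the list alone; median -0.24, camera adjusted p = 0.00699, and adjusted p = 0.172 with an estimated correlation). They included Gpr34 (-2.36) and P2ry13 (-1.16), receptors of microglia, Cd33 (-2.18), an inhibitory receptor, and Rhob (1.42), a small GTPase.

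In the same comparison 4 of 20 heat shock and immediate early genes rose, among them Fos (0.91), Dusp1 (0.89), Zfp36 (0.84) and Jun (0.51), with a median of 0.43 (4 adjusted over the list alone; camera adjusted p = 0.00913, and adjusted p = 0.172 with an estimated correlation). Of 24 genes of the integrated and ER stress response 4 rose and 3 fell (10 and 5 adjusted over the list alone; median 0.58, camera adjusted p = 0.0124, and adjusted p = 0.398 with an estimated correlation). The transcription factors Ddit3 (1.82) and Atf4 (1.00) rose, and the chaperones Dnajb9 (-1.04) and Hsp90b1 (-0.88) fell. Of 31 NF-kB target genes Gadd45b rose (2.04; 1 adjusted over the list alone; median 0.28, camera adjusted p = 0.0124, and adjusted p = 0.374 with an estimated correlation), and of 23 antigen presentation genes the peptide transporter gene Tap1 rose (0.62; 8 higher and 1 lower adjusted over the list alone; median 0.40, camera adjusted p = 0.00967, and adjusted p = 0.374 with an estimated correlation). Of 26 complement and phagocytic receptor genes 6 fell, among them the Fc receptor genes Fcgr2b (-1.19) and Fcgr3 (-0.86), Itgam (-0.94) and Msr1 (-0.84), with 7 lower and 3 higher adjusted over the list alone (median -0.31, camera adjusted p = 0.0478, and adjusted p = 0.374 with an estimated correlation). Of 26 glycolysis and hypoxia genes Ndrg1 (-2.33) and Pdk1 (-0.83) fell (2 adjusted over the list alone; median -0.52, camera adjusted p = 0.000218, and adjusted p = 0.374 with an estimated correlation). Without WT replicate 2 the heat shock (adjusted p = 0.0559) and NF-kB (0.0681) calls ended, without WT replicate 3 those of antigen presentation (0.0638) and ER stress (0.206), and without Tbk1het Tak1het replicate 2 that of complement (0.0915). The covariate for the mitochondrial share ended the NF-kB, complement, glycolysis, heat shock and mitochondrially encoded calls.

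The other 15 lists did not pass in Tbk1het Tak1het against WT. Among 32 components of the TNF-RIPK1-TBK1-TAK1 pathway Ripk1, Chuk (1.25) and Rnf31 (0.61) rose and Tbk1 fell, with 4 higher and 2 lower adjusted over the list alone (median 0.14, camera adjusted p = 0.135). Inflammatory cytokines and chemokines had a median of 0.27 (camera adjusted p = 0.206) and intrinsic apoptosis 0.16 (0.297), with 0 members called in either by edgeR. Disease-associated microglia genes had a median of -0.20 (0.087), with Cst7 (-1.25) and Cd52 (-1.08) lower, autophagy and lysosome genes -0.02 (0.23), with Lamp2 (-0.92) and Atg5 (-0.56) lower, and alternative activation genes -0.17 (0.703), with Tgfb1 (1.51) higher and Arg1 lower. Cholesterol biosynthesis had -0.12 (0.905), and the antioxidant response -0.10 (0.492), with Txnrd1 (1.25) higher and Sod1 and Cat (-0.52) lower. Markers of astrocytes had a median of 0.01, a mean of -0.56 and a test direction of lower (0.62). The medians were 0.87 for oligodendrocyte lineage markers (0.206), -0.77 for neuron markers (0.468), -1.65 for fibroblast, mural and endothelial markers (0.135) and -0.33 for border macrophage and monocyte markers (0.62), with 0 members called by edgeR. Other blood cell markers had 0.36 (0.905), with S100a8 (-2.41) lower, and sex-linked genes had 0.60 (0.492).

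**Figure D2:**
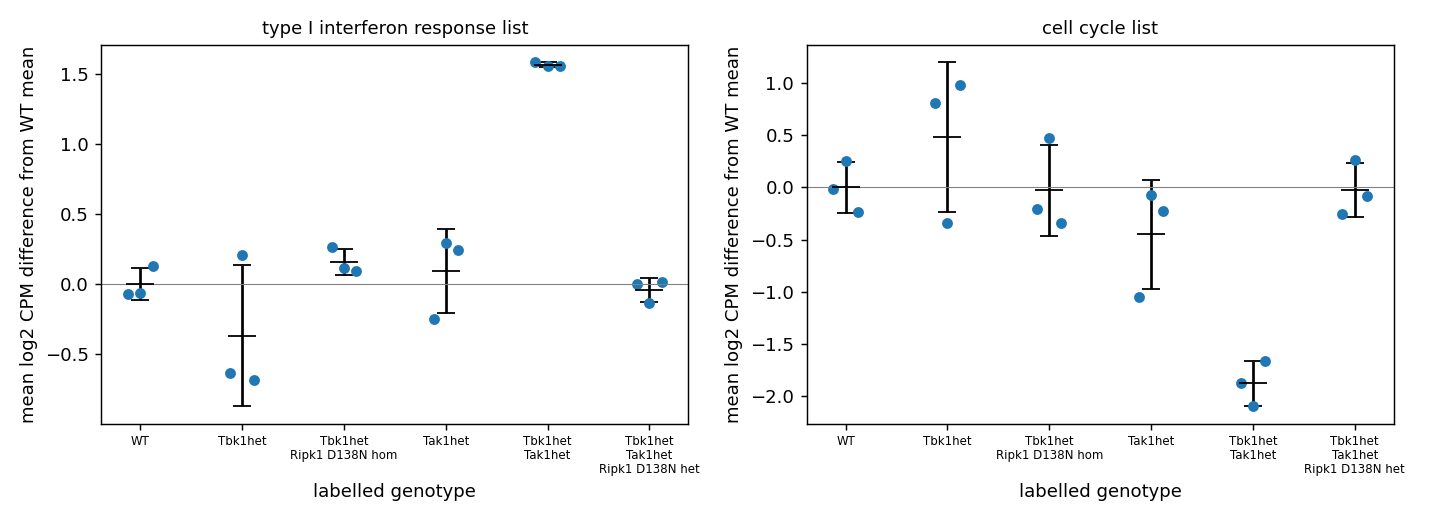
Mean log2 CPM of the type I interferon response and cell cycle lists in each of the 18 libraries, as a difference from the WT mean, by genotype. Points are libraries. The 3 Tbk1het Tak1het libraries lie at 1.59, 1.56 and 1.56 for the interferon list and at -1.87, -2.10 and -1.66 for the cell cycle list, and those labelled Tbk1het Tak1het Ripk1het lie between -0.25 and 0.26 for both.

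Tbk1het Tak1het against Tbk1het shows the Tak1 allele on a background of 1 lost Tbk1 allele. Interferon-induced genes rose, with Isg15 going from 2.54 ± 0.623 CPM (SD, n = 3) to 25.8 ± 0.369 (log2 fold change 3.34, adjusted p = 2.69e-06), and the chemokine gene Cxcl10 from 1.49 ± 0.511 to 16.8 ± 1.72 (3.49, adjusted p = 0.0003). Ifit3b (4.06), Mx1 (3.30) and Wrnip1 (3.68), a partner of the Werner helicase, rose too. Mki67 (-5.06), the mitotic kinase gene Mastl (-5.29), Shcbp1 (-4.95), the kinetochore gene Knl1 (-4.89) and the condensin gene Ncapg (-4.50) fell. Ripk1 rose by 1.70 (adjusted p = 0.015, and 0.0622 without Tbk1het Tak1het replicate 3). Of the interferon list 34 of 45 rose (38 adjusted over the list alone; median 1.64, camera adjusted p = 1.09e-40, and 0.00718 with an estimated correlation) and of the cell cycle list 25 of 35 fell (26 adjusted over the list alone; median -2.64, camera adjusted p = 1.83e-24, and adjusted p = 0.144 with an estimated correlation). The mitochondrial share was 2.01% ± 0.191 in Tbk1het, and 10 of 13 mitochondrially encoded genes fell (11 adjusted over the list alone; camera adjusted p = 6.42e-09, and adjusted p = 0.193 with an estimated correlation). In all 1974 genes were called, 866 higher and 1108 lower. The count was 140 with the mitochondrial share as a covariate, 1160 without Tbk1het replicate 1, and 1234 and 1071 without Tbk1het Tak1het replicates 1 and 3.

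Tbk1het Tak1het against Tak1het shows the Tbk1 allele on the Tak1 background. Ptprz1, a receptor phosphatase of glial cells, rose from 0.632 ± 0.432 to 13.5 ± 3.86 CPM (SD, n = 3; log2 fold change 4.37, adjusted p = 0.0192), and Mx1 (3.11), Oas2 (2.69), Ifit3b (2.40) and the cytoskeletal gene Dpysl3 (3.05) rose. S100a4 (-3.38), Mki67 (-3.79), Ccnb2 (-3.08), Alox5 (-3.29), an enzyme of leukotriene synthesis, and Tmem154 (-3.03) fell. Of the interferon list 26 of 45 rose (39 adjusted over the list alone; median 1.35, camera adjusted p = 3.87e-44, and 0.0049 with an estimated correlation). Of the ribosomal proteins 18 of 30 fell (28 adjusted over the list alone; median -0.54, camera adjusted p = 2.34e-35, and 0.0049 with an estimated correlation), and of the cell cycle list 9 of 35 (18 adjusted over the list alone; median -1.26, camera adjusted p = 2.53e-18, and adjusted p = 0.104 with an estimated correlation). Markers of the oligodendrocyte lineage were higher too, with a mean log2 difference from WT of 0.88 to 1.07 in the Tbk1het Tak1het libraries and -0.87 to -0.32 in the Tak1het libraries, 0 of 9 called by edgeR (3 adjusted over the list alone), a median log2 fold change of 0.86 and a camera adjusted p of 0.0119 (adjusted p = 0.104 with an estimated correlation, 0.162 under the stricter filter and 0.151 with the Y-linked covariate). The mitochondrial share was 1.12% ± 0.583 in Tak1het. In all 375 genes were called, 99 higher and 276 lower. The count was 158 with the mitochondrial share and 876 with Y-linked expression as a covariate, 568, 116 and 127 without Tak1het replicates 1, 2 and 3, and 111, 134 and 144 without Tbk1het Tak1het replicates 1, 2 and 3. Ptprz1 lost the call without Tak1het replicate 2 or 3 and without Tbk1het Tak1het replicate 2 or 3 (adjusted p from 0.055 to 0.0942), and Dpysl3 without Tak1het replicate 2 or 3 (0.0742 and 0.062). Mx1 and Ifit3b each lost it without 5 of the 6 libraries (up to 0.108 for Ifit3b), and Oas2 without Tak1het replicate 3 (0.0735) or Tbk1het Tak1het replicate 3 (0.0509). Alox5 lost it without Tbk1het Tak1het replicate 2 or 3 (0.0536 and 0.0576), and Ccnb2 without Tak1het replicate 2 or 3 (0.0923 and 0.062) or Tbk1het Tak1het replicate 1 or 2 (0.13 and 0.11).

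The interaction of Tbk1 and Tak1 heterozygosity tests whether the change with both alleles differs from the sum of the changes with each. Interferon-induced genes were higher than that sum, with a log2 difference of 3.37 for Ifit3b, 3.22 for Cxcl10 (adjusted p = 0.0156) and 3.13 for Isg15 (adjusted p = 0.000645). Cell cycle genes were lower, with -5.34 for Mki67 (adjusted p = 0.0091), -4.24 for Ncapg, -3.97 for Ccnb2 and -3.84 for Shcbp1. Ptprz1 (5.84), Dpysl3 (3.52) and Fscn1 (3.19), which bundles actin, were higher. So were markers of the oligodendrocyte lineage, with a median log2 difference of 3.44, 0 of 9 called by edgeR (2 adjusted over the list alone) and a camera adjusted p of 0.00275 (adjusted p = 0.0817 with an estimated correlation; under the stricter filter the median was 0.20 and the list did not pass). Whether these counts came from microglia or from other cells in the cultures was not tested. The mitochondrial gene mt-Nd3 was lower (-5.21), with means of 7.42 CPM in Tbk1het and 0.133 in Tbk1het Tak1het, where the fitted value depends on the prior count. Of the interferon list 11 of 45 were called higher (37 adjusted over the list alone; median 1.51, camera adjusted p = 1.97e-35, and 0.014 with an estimated correlation). Of the ribosomal proteins 15 of 30 were lower (27 adjusted over the list alone; median -0.65, camera adjusted p = 5.49e-27, and 0.014 with an estimated correlation), and of the cell cycle list 12 of 35 (23 adjusted over the list alone; median -2.12, camera adjusted p = 4.08e-19, and adjusted p = 0.111 with an estimated correlation).

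In all 235 genes passed the test of the interaction, 71 higher and 164 lower. Without WT replicates 1, 2 and 3 the count was 132, 100 and 53, without Tbk1het replicates 121, 712 and 74, without Tak1het replicates 413, 46 and 60, and without Tbk1het Tak1het replicates 59, 74 and 66. It was 19 with the mitochondrial share and 760 with Y-linked expression as a covariate, and 679 in DESeq2. Sex-linked genes passed as a list at the preset correlation, in the higher direction. The Tak1het libraries had few or no Y-linked reads, so sex is partly mixed with genotype in the interaction too. Cxcl10 and Mki67 passed with each library left out in turn. Ptprz1, Dpysl3, Ifit3b, Fscn1, mt-Nd3, Ncapg, Ccnb2 and Shcbp1 each lost the call with any of at least 6 of the 12 libraries left out. The highest adjusted p was 0.073 for Ptprz1 without Tak1het replicate 3, 0.109 for Dpysl3 and 0.114 for Fscn1 without Tak1het replicate 2, 0.103 for Ifit3b without Tbk1het Tak1het replicate 2, 0.0737 for mt-Nd3, 0.0869 for Ncapg and 0.111 for Ccnb2 without Tbk1het Tak1het replicate 1, and 0.104 for Shcbp1 without Tbk1het Tak1het replicate 3.

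Libraries labelled Tbk1het Ripk1hom were compared with Tbk1het, to ask what the loss of RIPK1 kinase activity changes when 1 Tbk1 allele is lost. Pirb, an inhibitory receptor of myeloid cells, rose from 39.7 ± 13.4 CPM (SD, n = 3) to 103 ± 41.2 (log2 fold change 1.37, adjusted p = 0.0461), and the transcription factor gene Myc rose from 16.1 ± 6.08 to 39.2 ± 8.12 (1.28, adjusted p = 0.0387). The costimulatory ligand gene Cd86 fell from 154 ± 69.4 to 55.3 ± 7.11 CPM (-1.48, adjusted p = 0.023), and the actin-bundling gene Pls3 fell from 196 ± 83.1 to 66.3 ± 7.44 (-1.56, adjusted p = 0.0178). The other named increases were Eng (2.30), a coreceptor for TGF-beta, the anion channel gene Lrrc8c (1.89), Coro2a (1.47), Rcc1l (1.41), Nfkbid (1.39), an NF-kB inhibitor, the potassium channel gene Kcnn4 (1.24) and Abcc5 (1.20). The other named decreases were the cystine transporter gene Slc7a11 (-2.75), the leukotriene synthase gene Ltc4s (-2.67), the lipid droplet gene Hilpda (-1.87), the arginine sensor gene Castor1 (-1.68), Bclaf3 (-1.59), Klhdc10 (-1.40), Ctla2b (-1.35) and Jmy (-1.33). Of the interferon list 0 of 45 passed in edgeR (4 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 7.86e-06, and adjusted p = 0.548 with an estimated correlation). The mitochondrial share was 0.822% ± 0.644 against 2.01% ± 0.191, and mitochondrially encoded genes had a median of -1.34 (0 called, 7 adjusted over the list alone; camera adjusted p = 6e-08, and adjusted p = 0.548 with an estimated correlation). In all 7 lists passed at the preset correlation. Cell cycle, glycolysis and hypoxia, and ER stress were among them, in the lower direction, and each turned direction under an alternative given below.

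In all 70 genes were called in that comparison, 38 higher and 32 lower. Tbk1 itself was at 105 ± 43.7 CPM (SD, n = 3) against 57.7 ± 7.55 (log2 fold change 0.87, adjusted p = 0.115), so the labelled genotypes and the Tbk1 level differ. The count was 0 without replicates 1 and 3 of Tbk1het Ripk1hom, which left 1 library. It was 3, 607 and 2 without Tbk1het replicates 1, 2 and 3, and 2, 98 and 5 without Tbk1het Ripk1hom replicates 1, 2 and 3. Each of the named genes lost the call with any of Tbk1het replicate 1, Tbk1het replicate 3 and Tbk1het Ripk1hom replicate 1 left out, and all but Bclaf3 without Tbk1het Ripk1hom replicate 3. Without Tbk1het Ripk1hom replicate 1 the adjusted p was 0.117 for Pls3, 0.152 for Myc and 0.247 for Nfkbid. It was 1 with the mitochondrial share and 4 with Y-linked expression as a covariate, 0 in a fit on the 6 libraries, and 490 in DESeq2.

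Against WT, libraries labelled Tbk1het Ripk1hom had 0 genes called by edgeR and 688 at an unadjusted p under 0.05, with 6 called by DESeq2 and 0 by limma-voom. The genes with the smallest p included Cd109, a surface protein, with 2.44 ± 1.97 CPM (SD, n = 3) against 12.0 ± 4.02 in WT (log2 fold change -2.29, adjusted p = 0.934). Il7r had 57.1 ± 8.30 against 101 ± 23.2 CPM, and Ptchd1, on the X chromosome, had 12.2 ± 1.59 against 4.47 ± 1.86 (both adjusted p = 0.934). Markers of fibroblast, mural and endothelial cells were lower as a group, with 0 of 11 called by edgeR (1 adjusted over the list alone), a median of -1.58 and a camera adjusted p of 0.000656 (adjusted p = 0.305 with an estimated correlation, and 0.191 without WT replicate 1 at the preset one). In all 5 lists passed at the preset correlation, and mitochondrially encoded genes and autophagy and lysosome genes, both in the lower direction, were among them.

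Libraries labelled Tbk1het Tak1het Ripk1het were compared with Tbk1het Tak1het, to ask what 1 kinase-inactive Ripk1 allele changes. Of the 816 genes called between Tbk1het Tak1het and WT, 62 that were higher fell here and 195 that were lower rose. The same Tbk1het Tak1het libraries enter both comparisons, which by itself favours opposite changes. Simulated data with no effect gave correlations of -0.53 to -0.48 between these fold changes. The libraries labelled Tbk1het Tak1het Ripk1het also had Tbk1 near the WT level, so these changes cannot be assigned to the Ripk1 allele. Ifit3 fell from 79.6 ± 2.74 CPM (SD, n = 3) to 8.42 ± 3.05 (log2 fold change -3.23, adjusted p = 0.0058) and Rsad2 from 82.5 ± 3.98 to 14.9 ± 7.00 (-2.47, adjusted p = 0.00278). Arg1 rose from 5.45 ± 0.887 to 77.7 ± 11.2 CPM (3.81, adjusted p = 0.00278), S100a4 from 3.46 ± 0.850 to 48.9 ± 8.04 (3.79), and S100a6, also a calcium-binding protein, from 6.22 ± 1.47 to 52.2 ± 2.72 (3.09, adjusted p = 0.000138). The cell cycle genes Ccnb2 (3.72), Ube2c (3.45), Mki67 (3.34), Ccnb1 (3.29), Anln (3.24), Shcbp1 (3.18) and Ccna2 (3.12) rose. The interferon-induced genes Mx1 (-3.15), Oas3 (-2.74), Ifit3b (-2.60), Ifit1 (-2.48), Phf11d (-2.47) and Ifit2 (-2.44) fell, as did Dusp5 (-2.47) and Trib3 (-2.49), a pseudokinase of the stress response. Lyz2 rose by 2.28 (adjusted p = 2.7e-05).

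Of the interferon list 27 of 45 fell in that comparison (39 adjusted over the list alone; median -1.56, camera adjusted p = 2.68e-54, and 0.00418 with an estimated correlation). Of the cell cycle list 17 of 35 rose (26 adjusted over the list alone; median 1.95, camera adjusted p = 5.05e-30, and adjusted p = 0.0708 with an estimated correlation). The mitochondrial share was 0.839% ± 0.406 (SD, n = 3) against 0.463% ± 0.0824. Of the homeostatic microglia list 5 of 26 rose, among them Cd33 (1.95), P2ry13 (1.47), Gpr34 (1.34) and the fractalkine receptor gene Cx3cr1 (0.79), with 5 higher and 1 lower adjusted over the list alone (median 0.25, camera adjusted p = 0.00894, and adjusted p = 0.149 with an estimated correlation). Of the ribosomal proteins 9 of 30 rose (16 adjusted over the list alone; median 0.32, camera adjusted p = 3.59e-13, and adjusted p = 0.0824 with an estimated correlation).

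In all 330 genes were called between these genotypes, 247 higher and 83 lower. Tbk1 was at 115 ± 7.93 CPM (SD, n = 3) in the libraries labelled Tbk1het Tak1het Ripk1het (log2 fold change 0.96, SE 0.25, adjusted p = 0.0503), so they differ from Tbk1het Tak1het in Tbk1 RNA as well as in the labelled Ripk1 allele. The count was 87, 93 and 159 without Tbk1het Tak1het replicates 1, 2 and 3, and 98 and 95 without Tbk1het Tak1het Ripk1het replicates 2 and 3. Arg1, S100a4, S100a6, Ube2c, Ccnb1, Ifit3, Oas3, Rsad2 and Phf11d passed with each library left out in turn. The other named genes lost the call without Tbk1het Tak1het replicate 1, with an adjusted p of 0.0695 for Ccnb2, 0.0794 for Mki67, 0.0679 for Anln, 0.0933 for Shcbp1, 0.0516 for Ccna2, 0.0766 for Mx1, 0.0612 for Ifit3b, 0.0746 for Trib3, 0.0769 for Ifit1, 0.0552 for Dusp5 and 0.0962 for Ifit2. All of these but Ccna2 also lost it without at least 1 more library, with the highest adjusted p 0.137 for Ifit2 without Tbk1het Tak1het Ripk1het replicate 3.

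Against WT, libraries labelled Tbk1het Tak1het Ripk1het had 0 genes called by edgeR and 1074 at an unadjusted p under 0.05, with 75 called by DESeq2 and 0 by limma-voom. The smallest p-values included Cetn3, a centrin of the centrosome, with 52.6 ± 3.01 CPM (SD, n = 3) against 91.0 ± 7.31 in WT, Ddx3x, an RNA helicase gene of the X chromosome, with 174 ± 19.7 against 294 ± 20.1, and Msantd4, with 52.6 ± 4.70 against 88.4 ± 9.20 (each adjusted p = 0.18). Mitochondrially encoded genes had a median of -0.60 (0 of 13 called by edgeR or adjusted over the list alone; camera adjusted p = 0.0072, and adjusted p = 0.987 with an estimated correlation). That call ended without WT replicate 1 (adjusted p = 0.0787), WT replicate 2 (0.235) or Tbk1het Tak1het Ripk1het replicate 1 (0.419).

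Fold changes were also compared between pairs of comparisons across the 13447 genes, which are not independent replicates. For Tbk1het against WT and Tak1het against WT the correlation was 0.40, and 20 simulated data sets with no effect and the same shared libraries gave 0.47 to 0.53, while the covariance was 0.40 against a simulated mean of 0.32, so the 2 measures differed in direction. For Tbk1het against WT and Tbk1het Ripk1hom against Tbk1het it was -0.62 (simulated -0.52 to -0.46; covariance -0.62 against -0.31). For Tbk1het Tak1het against WT and Tbk1het Tak1het Ripk1het against Tbk1het Tak1het it was -0.65 (simulated -0.53 to -0.48; covariance -0.69 against -0.33). In that last pair 62 genes rose and then fell, against 1.80 if the calls were independent, and 195 fell and then rose, against 9.64. The calls are not independent, because both comparisons use the Tbk1het Tak1het libraries. How much of the overlap this gives was not measured.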

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

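The corrections for the mitochondrial share, for GC content and length and for Y-linked expression, the tests of Tbk1 and Map3k7 levels, the test of a Cre driver in Lyz2 and the count of libraries kept together in the splits were chosen only after the results they address were seen. A spread beside a list median is the SE of the difference in mean list score between libraries under the same correction, not of that median. Beside the log2 fold change of a gene it is the SE of the gene test. Beside a percentage it is the SD of 3 libraries.

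In the test of the interaction of Tbk1 and Tak1 heterozygosity, 235 genes differed from the sum of both changes. Above that sum were Ptprz1 (log2 5.84), Dpysl3 (3.52), Ifit3b (3.37), Cxcl10 (3.22) and Fscn1 (3.19). Below it were Mki67 (-5.34), mt-Nd3 (-5.21), Ncapg (-4.24), Ccnb2 (-3.97) and Shcbp1 (-3.84), where the value of mt-Nd3 depends on the prior count. Of 100 splits of the 12 libraries, the real one included, 5 gave at least 235 genes, and the highest other gave 958. Chance is therefore not excluded for this count. By edgeR at least 235 genes were called in 4 of the 42 other splits with 2 Tbk1het Tak1het libraries in 1 group (median 0), the 1 other split that kept all 3 together gave 7, and the 56 that parted them gave 0. What sets the count of a split was not tested further.

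Of the 235 genes 11 were in the interferon list, 12 in the cell cycle list and 15 in the ribosomal protein list. Interferon genes were higher and cell cycle genes lower in Tbk1het Tak1het than in WT, with list medians of 1.48 (adjusted p = 0.0128 with an estimated correlation) and -2.05 (adjusted p = 0.137, so not past the threshold there). With the mitochondrial share as a covariate, which lowered the count of called genes from 816 to 211, the medians were 1.54 (spread 0.25) and -1.47 (spread 0.33). This argues against the low share of these libraries as the whole cause only as far as 1 slope holds for all genotypes. All Tbk1het Tak1het libraries had a low share, and libraries with doubted labels enter that slope. The same covariate moved Tbk1 in Tbk1het Tak1het against Tbk1het from 0.0358 to -0.81, though both are labelled Tbk1+/-. After correction for GC content and transcript length the list medians were 1.57 (spread 0.20) and -1.99 (spread 0.36). With Y-linked expression as a covariate they were 1.56 (spread 0.22) and -2.16 (spread 0.38). These values argue against GC content, length and Y-linked expression as the whole cause. A joint effect of the lost alleles may account for the pattern, as a hypothesis found and tested on the same data, and a difference between cultures or preparation days that the labels do not give stays open and untested. The column names carry codes that read as plate positions and sequencing indices. Each genotype holds its own stretch of both, so position and genotype cannot be told apart.

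The libraries labelled Tbk1het Tak1het Ripk1het differed from Tbk1het Tak1het in 330 genes and from WT in 0 by edgeR, with 1074 at an unadjusted p under 0.05 and 75 called by DESeq2. Tbk1 was higher than in Tbk1het Tak1het by 0.96 (log2, spread 0.25; unadjusted p = 0.00124, adjusted p = 0.0503), and each of these libraries lay above each Tbk1het and Tbk1het Tak1het library, as libraries with both Tbk1 alleles would. The difference from WT was -0.0533 (spread 0.25), which argues against a return of expression with 1 Ripk1 D138N allele that leaves Tbk1 at the -1.01 of a lost allele. Whether they carry the Tak1 allele stays open, since Map3k7 differed from WT by -0.62 (spread 0.32) in Tak1het and by -0.50 (spread 0.32) in these libraries, with means of 8.76 and 9.61 CPM against 13.5, and passed the test in neither. A return that includes Tbk1 RNA and libraries without the labelled alleles cannot be told apart, because both predict Tbk1 near the WT level, and in Tbk1het Ripk1hom, with 2 such alleles, Tbk1 was at 109%, 46.0% and 110% of the WT mean in replicates 1, 2 and 3 (spread 36.6).

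Lyz2 was at 49.2% of the WT mean in Tak1het (spread 10.99) and at 22.5% in Tbk1het Tak1het. In Tbk1het it was at 78.9%, with replicates 1, 2 and 3 at 71.4%, 106% and 59.0%. A Cre driver inserted in the Lyz2 gene, which the labels do not name, is a candidate explanation for a level near that of 1 allele in Tak1het. With 1 copy it leaves the lower level in Tbk1het Tak1het without a cause, and the labels give no number of copies. The 109% in the libraries labelled Tbk1het Tak1het Ripk1het goes against such a driver unless those libraries lack the Tak1 allele, so it stays open. The median log2 fold change of the 15 tested genes within 1 Mb of Lyz2 was 0.0844 (quartiles -0.21 and 0.32), which argues against a change along the whole stretch. Lyz1, the next tested gene, was the 1 of the 15 past the threshold in Tbk1het Tak1het against WT (-1.97, adjusted p = 0.00824; -0.17 in Tak1het against WT), so a change at Lyz1 and Lyz2 alone, or reads shared between these paralogs, stays open and untested.

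Other splits of the libraries were counted for each comparison. For the test of the 6 genotypes 1 of 100 splits, the real one, gave as many as 966 genes, and the highest other gave 98. This argues against chance for that count only if libraries can be exchanged. Libraries of a genotype may share a culture or preparation, which the splits cannot tell from genotype. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split and the highest other gave 7 and 1 genes for Tbk1het against WT, 2 and 0 for Tak1het against WT, 816 and 0 for Tbk1het Tak1het against WT, 1974 and 0 against Tbk1het, and 375 and 1 against Tak1het. They gave 70 and 49 for Tbk1het Ripk1hom against Tbk1het, 330 and 0 for Tbk1het Tak1het Ripk1het against Tbk1het Tak1het, and 0 and 0 for each of these Ripk1 genotypes against WT by edgeR, where DESeq2 called 6 and 75 and limma-voom 0, and 688 and 1074 genes had an unadjusted p under 0.05.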

How the results depend on the processing

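The fits with the mitochondrial share, GC content and length, or Y-linked expression, on libraries of low mitochondrial share, and without libraries of doubted label, and the simulated calls by expression level, were chosen after seeing the data. Of 146 gene values 105 were called and 41 were not. Of the 105 calls, 58 ended with some library left out, 50 with the mitochondrial covariate, 42 in limma-voom, 32 in a fit on the libraries compared, 23 with the Y-linked covariate, 17 with the replicate number as a block, 14 after the GC correction and 0 in DESeq2, where 13 of the 41 others gained one. Of 94 list calls 7 passed with an estimated correlation, 41 with fry, 54 with the mitochondrial covariate, 83 after the GC correction and 93 with the block. The replicate numbers do not pair the samples: in 26 of 90 cases the best correlated library of another genotype had the same number. The file holds counts, so no other pseudocount or quantile scaling was run. DESeq2, limma-voom, no filter and the fit on the libraries compared gave no list values. Weakly expressed genes were called less often in simulated data, where depth was not varied. A fold of 2 was called for 3.70% of genes up to the median CPM and 66.7% above it in Tbk1het against WT. The shares were 3.70% and 77.5% in Tbk1het Tak1het against WT, and 3.70% and 32.5% in the interaction. Except where fewer libraries or genes enter by construction, the cause of the changes below was not tested.

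DESeq2 called 2277 genes in the overall test, 98 for Tbk1het against WT, 82 for Tak1het against WT, 1421 for Tbk1het Tak1het against WT, 733 against Tak1het, 679 for the interaction, 490 for Tbk1het Ripk1hom against Tbk1het, 6 against WT, 743 for Tbk1het Tak1het Ripk1het against Tbk1het Tak1het and 75 against WT. Without a low-count filter these counts were 2850, 293, 251, 1404, 868, 927, 754, 59, 864 and 193. Limma-voom called 3 genes for Tbk1het and 1 for Tak1het against WT. The stricter filter called 14 and 1 there, and 119 for Tbk1het Ripk1hom against Tbk1het. A fit on the libraries compared called 0 for Tbk1het, 0 for Tak1het and 1365 for Tbk1het Tak1het against WT, 128 for the interaction, 0 for Tbk1het Ripk1hom against Tbk1het and 574 for Tbk1het Tak1het Ripk1het against Tbk1het Tak1het. The replicate block gave 149 for the interaction and 35 for Tbk1het Ripk1hom against Tbk1het. A log2 fold change of at least 1 left 4 genes for Tbk1het against WT, 420, 919 and 169 for Tbk1het Tak1het against WT, Tbk1het and Tak1het, 39 for Tbk1het Ripk1hom against Tbk1het and 194 for Tbk1het Tak1het Ripk1het against Tbk1het Tak1het.

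The mitochondrial covariate gave 207 genes in the overall test, 211, 140 and 158 for Tbk1het Tak1het against WT, Tbk1het and Tak1het, 19 for the interaction and 1 for Tbk1het Ripk1hom against Tbk1het. The GC correction gave 493 in the overall test, 11 for Tbk1het against WT, 130 for the interaction and 34 for Tbk1het Ripk1hom against Tbk1het. The Y-linked covariate gave 1525 in the overall test, 13 and 63 for Tbk1het and Tak1het against WT, 876 for Tbk1het Tak1het against Tak1het, 760 for the interaction, 4 for Tbk1het Ripk1hom against Tbk1het and 684 for Tbk1het Tak1het Ripk1het against Tbk1het Tak1het. The libraries of low mitochondrial share, with 1 library left in WT, Tak1het and Tbk1het Tak1het Ripk1het that is assumed to vary like the others, gave 523 for Tak1het against WT. Without the doubted Tbk1het Ripk1hom libraries, which leaves 1 under the same assumption, 0 genes were called against Tbk1het.

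With each library left out in turn, the counts ranged from 320 to 1336 in the overall test, 1 to 334 for Tbk1het and 0 to 7 for Tak1het against WT, 288 to 614, 1071 to 2213 and 111 to 568 for Tbk1het Tak1het against WT, Tbk1het and Tak1het, 46 to 712 for the interaction, 2 to 607 for Tbk1het Ripk1hom against Tbk1het, and 87 to 435 for Tbk1het Tak1het Ripk1het against Tbk1het Tak1het. The number of lists called ranged from 2 to 11 for Tbk1het, 3 to 7 for Tak1het, 1 to 11 for Tbk1het Ripk1hom and 0 to 2 for Tbk1het Tak1het Ripk1het against WT.

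With an estimated correlation the lists called were 0 for Tbk1het, 0 for Tak1het and 1 for Tbk1het Tak1het against WT, 1 and 2 for Tbk1het Tak1het against Tbk1het and Tak1het, 2 for the interaction, 0 for Tbk1het Ripk1hom against Tbk1het and 0 against WT, and 1 for Tbk1het Tak1het Ripk1het against Tbk1het Tak1het and 0 against WT. Fry called 0, 1 and 7 against WT in the first 3 of these, 8 for the interaction, 0 and 0 for Tbk1het Ripk1hom, and 5 and 0 for Tbk1het Tak1het Ripk1het. The mitochondrial covariate gave 7 lists for Tbk1het against WT, 7 for Tbk1het Tak1het against WT, 4 for Tbk1het Ripk1hom against Tbk1het and 4 for Tbk1het Tak1het Ripk1het against WT. For that last comparison the GC correction and the stricter filter gave 0. For Tbk1het Ripk1hom against WT the Y-linked covariate, the stricter filter and the libraries of low mitochondrial share gave 2 each. For Tak1het against WT the stricter filter gave 3 and the libraries of low mitochondrial share 14, and without the doubted libraries Tbk1het Ripk1hom against Tbk1het had 4. Under the stricter filter the correlations of fold changes were 0.08, -0.76 and -0.83 for the 3 pairs of comparisons in the order reported.

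The following gene values turned their sign, and none of them was called in the reported test. Map3k7 in Tbk1het Ripk1hom against WT was -0.0027 in DESeq2, -0.0026 with its size factors, -0.0419 with the block, -0.0293 with the mitochondrial and -0.0390 with the Y-linked covariate, -0.62 in libraries of low mitochondrial share and -0.14 with a library left out. Map3k7 against Tbk1het was -0.0914 and -0.16 with these covariates, -0.0030 in limma-voom and -0.0508 with a library left out. In Tbk1het against WT Map3k7 was 0.0621 and 0.12 with the covariates, 0.0204 in limma-voom and 0.0482 with a library left out, and Ripk1 was 0.20, 0.17 and, with a library left out, 0.0225. The mitochondrial covariate gave Tbk1 -0.81 for Tbk1het Tak1het against Tbk1het and -0.59 for the interaction, and a left-out library -0.0527 and -0.0161. Libraries of low mitochondrial share gave Lyz2 0.0916 in Tbk1het Ripk1hom against WT and Ripk1 0.0683 in Tbk1het Tak1het Ripk1het against Tbk1het Tak1het. Without the doubted libraries Tbk1 was -0.0716 and Lyz2 -0.0393 in Tbk1het Ripk1hom against Tbk1het. With a library left out Tbk1 was 0.0437 in Tak1het, 0.0005 in Tbk1het Ripk1hom and 0.11 in Tbk1het Tak1het Ripk1het against WT, Ripk1 was -0.0089 and Lyz2 0.0094 in Tbk1het Ripk1hom against WT, and Map3k7 was 0.0041 and 0.0333 in Tbk1het Tak1het against WT and Tbk1het and 0.0975 in Tbk1het Tak1het Ripk1het against Tbk1het Tak1het.

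The following lists turned the direction of their test, and their medians under the alternative were these. In Tbk1het Ripk1hom against Tbk1het cell cycle had -0.12 and glycolysis -0.0217 with the mitochondrial covariate, -0.33 and -0.0557 without the doubted libraries, and glycolysis had 0.11 and ER stress 0.15 with the Y-linked covariate. The Y-linked covariate gave sex-linked genes -0.41 in Tak1het against WT, 0.23 in Tbk1het Tak1het against Tak1het and 0.64 in the interaction. The stricter filter gave astrocyte markers -0.15 in Tak1het against WT. Libraries of low mitochondrial share gave sex-linked genes 4.35 in Tak1het against WT, autophagy 0.0628 in Tbk1het Ripk1hom against WT, and disease-associated microglia -0.0165 and mitochondrially encoded genes -0.33 in Tbk1het Tak1het Ripk1het against Tbk1het Tak1het. Mitochondrially encoded genes had 0.27 in Tbk1het Ripk1hom against WT without the doubted libraries. With a library left out, cholesterol biosynthesis in Tbk1het against WT had a median from 0.0451 to 0.62, the lowest and the turned direction without Tbk1het replicate 1.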

Other observations

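In libraries labelled Tbk1het Tak1het Ripk1het against Tbk1het Tak1het, Dusp1, a phosphatase of stress kinases, fell by 1.13 on the log2 scale (adjusted p = 0.00922), as 1 of 20 heat shock and immediate early genes (1 higher and 5 lower adjusted over the list alone; median -0.37, camera adjusted p = 0.00108, and adjusted p = 0.0824 with an estimated correlation). Of 26 complement and phagocytic receptor genes 4 rose (6 higher and 1 lower adjusted over the list alone; median 0.32, camera adjusted p = 0.0225, and adjusted p = 0.382 with an estimated correlation), and of 26 glycolysis and hypoxia genes 2 rose (6 adjusted over the list alone; median 0.64, camera adjusted p = 1.59e-07, and adjusted p = 0.348 with an estimated correlation). The Tbk1 level of these libraries was near that of WT.

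Lyz1, a paralog next to Lyz2 named after its values were seen, fell from 54.9 ± 8.64 CPM (SD, n = 3) in WT to 13.9 ± 0.859 in Tbk1het Tak1het (log2 fold change -1.97, adjusted p = 0.00824; not refitted with libraries left out) and was at 48.8 ± 24.1 CPM in Tak1het. The first and second principal components held 17.1% and 8.52% of the variance between libraries. The first followed the mitochondrial share. It ran from 8.84 to 57.8 in the 8 libraries with a low share and from -56.3 to -9.51 in the others. All Tbk1het Tak1het libraries had a low share and all Tbk1het libraries did not, so share and genotype cannot be told apart between these 2 genotypes. By correlation over genes, each Tbk1het Tak1het library was closest to another library of its genotype. The libraries labelled Tbk1het Tak1het Ripk1het were closest to Tbk1het Ripk1hom replicate 1, WT replicate 2 and WT replicate 1. Every other genotype also had a library closest to another genotype. These were WT replicate 3, Tbk1het replicate 2, Tak1het replicate 1 and Tbk1het Ripk1hom replicates 1 and 2.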
